A study of Rattus norvegicus with 12 samples.

How the data were processed

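RNA was extracted from rat muscle with a column kit and sequenced as paired ends by a commercial service, per the labels' protocols. STAR and DESeq2 are named in the submitters' processing notes, without versions. The genome build and annotation used for alignment are not given in the sources used here. The gene identifiers in the deposited tables are those of mouse.

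Samples were grouped by muscle and treatment from their titles, which also give the replicate numbers. Before the data were examined, the planned comparisons were fixed as tests across all genes within each muscle, an interaction test across muscles, and tests of fixed gene lists. The plan also held a comparison of the control muscles and a check for duplicate libraries. The correlation and the overlap of the treatment responses of back and leg muscle were planned too. None of these was run. A column was to be used only where its name matched the labels of one sample or one group. All 12 columns of values failed this requirement, because their codes ST and WT do not occur as treatment labels, and the 12 columns were left out. Column order and expression values were not used to assign them.

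The headers and gene identifiers of the 2 tables were read with Python 3.11.15. Each identifier was looked up in all fields of the rat reference table, with and without its version suffix. The reference is of rat and lists an Ensembl identifier for 0 of its 47357 genes. For both reasons this lookup could not pair mouse Ensembl identifiers with symbols. A gene reference for mouse would be needed, and none was used here. Depth per sample is not given, since no column was assigned to a sample.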

Results

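Bulk RNA-seq was used to profile muscle at the site of an implantation or surgery in Long-Evans rats, an outbred laboratory strain. The sample labels placed 12 samples in 4 groups of 3 biological replicates. Back muscle and leg muscle were each sampled after injection of a magnetic fluid (MFIT) and in controls given no treatment or sham surgery (NT). The series describes the aim as measuring immune, inflammatory and fibrotic responses to the fluid. It names collection at 7 and 14 days after surgery, with 3 replicates per day and condition. The sample labels give no day and differ only by muscle, treatment and replicate. The day on which each sample was collected is therefore unknown here. Muscle may coincide with collection day, or days may be mixed within groups. If muscle coincides with day, differences between the muscles could not be told apart from differences between days.

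The expression values were held in 2 tables, one per muscle, each with 6 columns of values. Within each, 3 columns carried the code ST and 3 the code WT, each with a replicate number. The labels describe the samples as MFIT or NT. The code ST stood in the labels of 0 of the 12 samples. The code WT stood in the labels of all 12 samples, as part of their genotype, and therefore did not separate treated from control animals. The sources used here do not state which code denotes the injected muscle, or that the columns hold the 12 labelled libraries. Either code could be read as a control, and the direction of every treatment difference would depend on that reading. The table fixes the muscle of a column, but the columns that hold control muscle are unknown too.

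For this reason no column was assigned to a treatment group. The comparison of MFIT with NT in back muscle, the same comparison in leg muscle, the difference between these responses, and the difference between the control muscles were not analysed here. No fold change, p-value or count of changed genes is given for any of them.

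Each table listed 56953 genes, and both tables listed the same genes in the same order. All 56953 identifiers in each table were mouse Ensembl gene identifiers, although the tissue is labelled as rat. The sources used here do not state whether rat reads were counted against a mouse annotation. The genes were preceded by 4 rows that name classes of reads (unmapped, multimapping, without a feature and ambiguous). On inspection, the unmapped row held most of the reads in every column. The sizes of these rows were not analysed further, so the share of reads that mapped is not given. The counts therefore have limits beyond the missing treatment labels and gene symbols. The rat reference table used here lists 47357 genes of the GRCr8 assembly, and 0 of the 56953 identifiers were found in it. That outcome was fixed in advance, because the reference lists no Ensembl identifiers. No gene symbol was assigned. The lists of immune, fibrosis, muscle and cell type genes fixed in advance were not tested, for lack of both symbols and columns assigned to a group.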

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

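The lookup of gene identifiers was chosen after seeing the data. It found 0 of the 56953 identifiers of each table in the rat reference with their version suffix, and 0 without it. The reference lists no Ensembl identifiers, so both lookups had to give 0 and say nothing about stability. The alternatives planned for the treatment comparisons (other normalizations, filters, tests and thresholds, leaving out each replicate, and other gene list tests) were not run, because no column was assigned to a group. No paired analysis was possible under the rule that only columns matched to a labelled sample or group are used, because none matched. A comparison of the ST and WT columns within a muscle can be computed without a treatment direction, paired by replicate number or not. That comparison was left out by the same rule. The labels do not say that a replicate number marks a shared animal, litter or day.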
